A study of Homo sapiens with 16 samples.

How the data were processed

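RNA of U937 cells, an established human cell line, was measured on 16 arrays with 2 channels each. Per the labels, each array paired 2 of 4 RNA sources, cytoplasmic or polysomal RNA of intact or PMA-treated cells (32 nM, 48 h), and each of the 4 comparisons held 2 numbered replicates with a dye-swapped array each. The scanner, image software, background correction, within-array normalization, polysome preparation and the dyes of the channels were not given in the sources used here. The authors deposited 1 value per probe and array, taken here as a log10 ratio of the channels. Base 10 is the convention for the array type and number format and is not stated in the file headers or labels, so every fold change rests on it. Values were multiplied by 3.32 to give log2 ratios.

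Medians of the deposited values lay near 0 on every array, so some centring had been done, by a method that stays unknown. In intact cells, polysomal over cytoplasmic RNA, they were -0.0105 and -0.00939 on the forward arrays and -0.0269 and -0.0136 on the swapped arrays of replicates 1 and 2. In PMA-treated cells they were -0.00758 and -0.0300, and -0.0239 and -0.0116. For PMA over intact cells in cytoplasmic RNA they were -0.00882 and -0.00489, and -0.0101 and -0.0296, and in polysomal RNA 0.0133 and -0.00941, and -0.0107 and -0.0116. The direction of the ratio is not stated either. It was taken as channel 2 over channel 1, the likely order given that forward arrays have cytoplasmic or intact RNA in channel 1 and that genes such as MMP9 then rose with PMA. Scale, centring and direction therefore all rest on convention or on the values.

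The table held 19061 probes with no missing value. An annotation table gave 1 gene symbol to 15695 probes, several to 4 and none to 3362, and the 3366 without 1 symbol were left out. Probes of 1 gene were averaged (650 genes had over 1), which left 14227 genes. Each array was centred on its median, swapped arrays were turned in sign, and the 2 arrays of a dye-swap pair were averaged, since a dye swap is technical. Centring makes every ratio relative to the array's median, so a shift shared by most messages, such as a general move of RNA on or off polysomes, would not show. No intensities were used here, so signal over background is unknown, and the number of arrays limits the precision.

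The 8 pair means entered limma (version 3.58.1 in R 4.3.3) with 1 coefficient per comparison, 4 residual degrees of freedom and 2.04 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The change of the polysomal over cytoplasmic ratio with PMA was the mean of the difference of both PMA comparisons and the difference of both fraction comparisons, tested as a contrast of the same model. Before the data were examined, the groups, the tests, 19 gene lists with 750 entries (676 measured), the alternatives and the rule for named genes were fixed. The lists covered macrophage markers, cytokines and chemokines, NF-kB and immediate early genes, myeloid progenitor and granule genes, cell cycle and DNA replication, MYC and ribosome biogenesis, cytoplasmic ribosomal proteins, translation factors, interferon response, the endoplasmic reticulum and secretory pathway, the mitochondrial respiratory chain, cholesterol biosynthesis, iron and ferritin, the proteasome, the lysosome, lymphoid, erythroid and megakaryocyte, and fibroblast and epithelial markers, and nuclear-retained RNAs. Macrophage markers and lysosome genes shared 6 entries. The 18 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of each comparison. Of 33 list calls in 90 tests, 3 held with an estimated correlation, those of macrophage markers, cytokines and NF-kB genes in cytoplasmic RNA.

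Named genes were the 10 highest and 10 lowest called genes of each comparison with the same sign on all 4 arrays, up to 4 called members of each list with the largest ratio (or 2 with the smallest p where none was called), and MYC, MMP9 and CD14. A gene outside this rule is said to be named after its values were seen.

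The model was tested on simulated data with the measured spread of the 14227 genes, with 50 genes changed at each size. For PMA in cytoplasmic RNA it recovered 14, 35, 43 and 49 of 50 genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 10 false calls. For polysomal RNA it recovered 40, 45, 50 and 49 at changes of 1, 2, 4 and 6, with 10 false calls, and for the fraction comparisons 16, 31, 45 and 49 in intact cells (0.5 to 3, 11 false calls) and 38, 43, 50 and 49 in PMA-treated cells (1 to 6, 16 false calls). The change of ratio recovered 16, 35, 44 and 49 at 0.5 to 3, with 14 false calls. In the same order, all calls numbered 151, 194, 152, 196 and 158. In this 1 simulated data set the false share thus lay above the threshold of 0.05 in each comparison. In 20 simulations with no change, independent errors gave a median of 0 calls in each comparison. Errors shared by arrays of the same RNA gave a median of 21.5 calls (0 to 51) for the change of ratio and 0 for the others. All errors were drawn separately for each gene, so errors shared between genes were not simulated. The simulated dye bias also cancelled in every pair. In the data, the forward array of replicate 1 in polysomal RNA, PMA over intact cells, carried it with the opposite sign (slope -1.24). The figures for polysomal RNA and for the change of ratio therefore came from a cleaner setting than the data.

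Alternatives fixed beforehand were no centring, scaling to one spread, each probe on its own, all 16 arrays with a dye coefficient, either dye orientation alone, a closed loop, the arrays of a comparison alone, a robust variance prior, the replicate number as a block, leaving out each replicate, and a 2-fold minimum. For the lists they also included an estimated correlation and limma's fry, which tests the list's own members and not against other genes. Alternatives chosen after the data were seen were the removal of a dye bias from 1 replicate, leaving out its forward array, the dye coefficient turned for it, unnamed probes included, values read in base 2, crossed replicate numbers, and 1 value per replicate number.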

Results

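U937 is an established human line of monocyte-like cells that takes on macrophage-like features under phorbol 12-myristate 13-acetate (PMA), a phorbol ester that activates protein kinase C. Cells were left intact or given 32 nM PMA for 48 h, and RNA was taken from the cytoplasm and from polysomes, the strings of ribosomes on messages under translation. The stated aim was to look at control after transcription in this differentiation model. The 4 RNA sources were hybridised against each other on 16 arrays of 2 colours, which formed a loop of 4 comparisons. PMA-treated cells were set against intact cells in cytoplasmic and in polysomal RNA, and polysomal RNA was set against cytoplasmic RNA in intact and in PMA-treated cells. Each comparison had 2 replicates, each the mean of 2 dye-swapped arrays, so n = 2 throughout. No label said that the replicates were separate cultures, so the p-values measured only the spread between these samples, which may be technical, and the number of arrays limited the precision. Values are log2 ratios ± the standard error (SE) of the limma fit, whose spread was pooled over the 8 dye-swap pairs. Deviations of the replicates correlated at -0.782 and -0.804 between comparisons that shared PMA cytoplasmic or intact polysomal RNA. The model took all pairs as independent, so the adjusted p of every comparison may be too small. The likely direction was channel 2 over channel 1, taken from the usual order of such ratios, from control RNA lying in channel 1 of the forward arrays and from genes such as MMP9 then rising with PMA. The direction of MMP9 and of the macrophage markers below is therefore not independent of that choice. With the opposite order every sign would turn, and the counts of higher and lower genes below would change places. The log base of 10 was taken by convention, and in base 2 every log2 ratio would be smaller by a factor of 3.32.

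In cytoplasmic RNA, PMA raised members of the macrophage, chemokine and lysosome lists and lowered 2 genes of the progenitor and granule list. ZFP36L1, an RNA-binding protein that promotes decay of messages with AU-rich elements, rose 27.9-fold (4.80 ± 0.33, n = 2, adjusted p = 0.00613). SPP1, which encodes the secreted protein osteopontin, rose 18.6-fold (4.22 ± 0.34, adjusted p = 0.00836), and the chemokine gene CCL7 rose 15.2-fold (3.92 ± 0.14, adjusted p = 0.00118). The collagenase gene MMP1 rose 13.9-fold (3.80 ± 0.35, adjusted p = 0.0120). CTSG, which encodes the granule protease cathepsin G, fell by 2.90 ± 0.26 on the log2 scale (adjusted p = 0.0117), and GFI1, a transcriptional repressor of myeloid progenitors, fell by 1.80 ± 0.23 (adjusted p = 0.0256).

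Among the macrophage markers fixed beforehand, 17 of 51 measured members rose over all genes, none fell, and 27 rose when adjusted over the list alone. Their median was 0.50, and the list shifted upward (adjusted p = 3.31e-17, and adjusted p = 0.0321 with an estimated correlation). Besides SPP1, the members VIM, an intermediate filament gene, at 8.01-fold, LGALS3, which encodes galectin-3, at 2.87 ± 0.32, and the gelatinase gene MMP9 at 2.48 ± 0.31 (adjusted p = 0.0227) rose. NCF1, a subunit of the phagocyte oxidase, also rose (3.94 ± 0.36), although near-identical pseudogene copies could not be told apart on its probe. CD14, the endotoxin coreceptor, stood at 0.26 ± 0.18 (adjusted p = 0.510). Of 39 cytokines and chemokines 5 rose, and 12 did so adjusted over the list alone, with IL1B at 2.39 ± 0.33 and CXCL8, the neutrophil chemokine interleukin-8, at 1.53 ± 0.15. The list shifted upward (median 0.19, adjusted p = 6.25e-07, and adjusted p = 0.0321 with an estimated correlation). The NF-kB and immediate early genes had 9 of 41 members higher, 17 adjusted over the list alone, among them BCL2A1, which protects from apoptosis, at 3.02 ± 0.12 and the cyclin-dependent kinase inhibitor CDKN1A at 1.94 ± 0.26. Their median was 0.46 (adjusted p = 1.21e-11, and adjusted p = 0.0321 with an estimated correlation). In the lysosome list 7 of 40 members rose, 12 adjusted over the list alone, led by the protease gene CTSB at 2.36 ± 0.23 and PSAP, the saposin precursor, at 1.38 ± 0.11. Its median was 0.33 (adjusted p = 6.14e-07, but adjusted p = 0.189 with an estimated correlation).

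Of 20 myeloid progenitor and granule genes, CTSG and GFI1 fell over all genes and 8 fell adjusted over the list alone (median -0.32, adjusted p = 8.03e-05, but adjusted p = 0.138 with an estimated correlation). Cell cycle and DNA replication genes had a median of -0.86 over 68 members, which was -0.42 in replicate 1 and -1.29 in replicate 2. None passed over all genes in limma, where 2368 of all genes had an unadjusted p under 0.05, and 21 fell adjusted over the list alone. That list shifted downward (adjusted p = 1.12e-17, but adjusted p = 0.315 with an estimated correlation), with the thymidine kinase gene TK1 at -1.31 ± 0.22 (adjusted p = 0.0540). The MYC and ribosome biogenesis list was similar in size of shift, with a median of -0.87 over 34 members, 0 passing over all genes and 16 lower adjusted over the list alone (adjusted p = 8.97e-12, but adjusted p = 0.2997 with an estimated correlation). The median of that list was -0.64 in replicate 1 and -1.22 in replicate 2. MYC itself stood at -1.96 ± 0.91 (adjusted p = 0.358). Smaller downward shifts were called for translation factors, the endoplasmic reticulum and secretory pathway, and the proteasome, with medians of -0.36, -0.19 and -0.24. Their adjusted p were 2.16e-04, 3.68e-04 and 3.63e-04, and adjusted p = 0.490, adjusted p = 0.486 and adjusted p = 0.490 with an estimated correlation. Replicate 1 gave medians of -0.14, -0.10 and -0.04 and replicate 2 gave -0.49, -0.38 and -0.39, so these shifts lay mostly in replicate 2. Members that fell over all genes were the initiation factors EIF3B and EIF5A at -1.28 ± 0.15 and -1.14 ± 0.18, SSR1 and the chaperone gene CALR at -1.21 ± 0.17 and -0.85 ± 0.10, and the proteasome subunit gene PSMD1 at -1.35 ± 0.11. Adjusted over the list alone, 3 of 43 translation factors, 3 of 48 secretory genes and 1 of 31 proteasome genes fell. In the interferon response list 1 of 41 members rose, the lysosomal thiol reductase gene IFI30 at 1.33 ± 0.18, and 3 rose adjusted over the list alone. Its median was 0.12 (adjusted p = 0.00188, but adjusted p = 0.291 with an estimated correlation).

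No shift was called for cytoplasmic ribosomal proteins (median 0.14, adjusted p = 0.152), the mitochondrial respiratory chain (median -0.10, adjusted p = 0.0526), cholesterol biosynthesis (median 0.37, adjusted p = 0.0599) or iron and ferritin genes (adjusted p = 0.805). The iron list had a median of 0.05 but a mean of -0.01 and a test that pointed down. Markers of other cell types also showed no called shift, with medians of 0.09 for lymphoid, 0.04 for erythroid and megakaryocyte, and 0.08 for fibroblast and epithelial genes (adjusted p = 0.106, 0.152 and 0.152). Adjusted over the list alone, 1 cholesterol gene rose and 1 iron gene fell, and 0 ribosomal protein, respiratory chain, lymphoid, or erythroid and megakaryocyte genes passed. FAP, the fibroblast activation protein gene of the last list, nevertheless rose over all genes and adjusted over the list alone (2.51 ± 0.30, adjusted p = 0.0220).

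Over all 14227 genes, limma called 256 changed by PMA in cytoplasmic RNA, 190 higher and 66 lower, of which 155 changed at least 2-fold. The 2 dye-swapped arrays of replicate 1 correlated at only r = 0.112 across probes once turned, against 0.511 in replicate 2. Pairs of the other comparisons gave 0.424 to 0.904. Scaling the arrays to one spread raised the count to 1057 and turned the balance to 514 higher and 543 lower. Leaving out either replicate of this comparison called 0 genes, with 1944 genes at an unadjusted p under 0.05 without replicate 1 and 770 without replicate 2, and leaving out either replicate of the fraction comparison in intact or in PMA-treated cells called 130 or 142.

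In polysomal RNA, PMA raised members of the chemokine, macrophage and lysosome lists and lowered 3 genes of the progenitor and granule list. ZFP36L1 rose 60.7-fold (5.92 ± 0.33, n = 2, adjusted p = 0.00119), and RGS1, a regulator of G-protein signalling, rose 46.3-fold (5.53 ± 0.28, adjusted p = 0.00112). The matrix metalloproteinase gene MMP19 rose 46.1-fold (5.53 ± 0.22, adjusted p = 3.18e-04). MLC1, a membrane protein gene, fell by 3.64 ± 0.47 (adjusted p = 0.0149), and ZFP36L2, a relative of ZFP36L1, fell by 2.64 ± 0.36 (adjusted p = 0.0165). CTSG fell by 2.75 ± 0.26 (adjusted p = 0.00584). The cancer-testis genes VCX2, VCX3A and VCX3B fell, to -2.78, -2.94 and -2.76, but these close copies could not be told apart on the arrays.

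Of the 51 macrophage markers 22 rose and 2 fell over all genes, and 28 rose and 2 fell adjusted over the list alone. SPP1 reached 4.55 ± 0.34, the scavenger receptor gene CD36 3.63 ± 0.70, the lipid-binding protein gene FABP4 3.36 ± 0.62 and MMP9 3.25 ± 0.31. The 2 that fell, named after their values were seen, were the protease gene CTSZ at -1.38 and the scavenger receptor gene MARCO at -0.36. Among cytokines and chemokines 7 of 39 rose, 11 rose and 1 fell adjusted over the list alone, with CCL7 at 4.01 ± 0.14, CCL2 at 3.72 ± 0.55 and IL1B at 3.61 ± 0.33. Of the NF-kB and immediate early genes 10 of 41 rose, 18 rose and 1 fell adjusted over the list alone, with the stress-induced factor gene ATF3 at 3.67 ± 0.26 and the phosphatase gene DUSP6 at 3.27 ± 0.43. The lysosome list had 13 of 40 members higher and CTSZ lower, with 19 higher and 1 lower adjusted over the list alone, led by the protease genes CTSB at 3.17 ± 0.23 and CTSH at 2.79 ± 0.19. Medians of these 4 lists were 0.78, 0.12, 0.38 and 0.56, and all shifted upward (adjusted p = 1.22e-14, 3.95e-05, 4.16e-08 and 4.40e-10). None of these calls held with an estimated correlation, where macrophage markers gave adjusted p = 0.0585, cytokines adjusted p = 0.0620, NF-kB genes adjusted p = 0.0644 and lysosome genes adjusted p = 0.122 with an estimated correlation.

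The lists of progenitor and granule genes, cell cycle genes and MYC and ribosome biogenesis genes shifted downward, with medians of -0.18, -0.75 and -0.82 (adjusted p = 0.00396, 2.51e-10 and 5.14e-08). The calls were lost at adjusted p = 0.258, adjusted p = 0.498 and adjusted p = 0.498 with an estimated correlation. Replicates 1 and 2 gave medians of -0.24 and -0.44, -0.99 and -0.44, and -0.51 and -0.78 in the same order. Over all genes 3 of 20 progenitor and granule genes fell, CTSG, GFI1 and the myeloid factor gene CEBPA (-1.05 ± 0.18), and adjusted over the list alone 5 fell and 1 rose. TK1 was the 1 of 68 cell cycle genes that fell (-1.71 ± 0.22, adjusted p = 0.0151), also adjusted over the list alone. Of 34 MYC and ribosome biogenesis genes NOP16 and NHP2 fell, at -2.10 ± 0.38 and -1.82 ± 0.30, and 6 fell adjusted over the list alone. MYC stood at -2.40 ± 0.91 (adjusted p = 0.216).

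Ribosomal protein genes had a median of -0.58 in polysomal RNA with 0 of 67 members passing, over all genes or adjusted over the list alone, while limma gave 2889 of all genes an unadjusted p under 0.05. Their list was called lower (adjusted p = 0.00175, but adjusted p = 0.722 with an estimated correlation), with a median of 0.06 without replicate 2 and -1.28 without replicate 1 of this comparison. Respiratory chain genes had a median of -0.24 (adjusted p = 0.0473, but adjusted p = 0.722 with an estimated correlation), which was 0.06 without replicate 2, and 1 of 65 fell, the cytochrome oxidase subunit gene COX6C (-0.97 ± 0.10), also adjusted over the list alone. Translation factors had a median of -0.36 with 0 of 43 passing either way (adjusted p = 0.00396, but adjusted p = 0.625 with an estimated correlation). The ferritin light chain gene FTL rose (1.03 ± 0.17, adjusted p = 0.0272), as 1 of 3 of the 13 iron genes that passed, while 3 rose and 1 fell adjusted over the list alone (median 0.04, adjusted p = 0.173 in limma's camera, but higher in limma's fry, which tests the members alone, at adjusted p = 0.0363). In the proteasome list PSMA1 and PSMC1 rose (0.87 ± 0.14 and 0.85 ± 0.11) and PSMD1 fell (-1.60 ± 0.11), with 5 higher and 1 lower of 31 adjusted over the list alone. Its median was -0.02 while the test pointed up (adjusted p = 0.368). Interferon response genes had 2 higher and 1 lower of 41 (adjusted p = 0.173), secretory genes 1 lower of 48 (adjusted p = 0.251) and cholesterol genes 0 of 20 passing (adjusted p = 0.962), which became 2 and 1, 0, and 0 adjusted over the list alone. Lymphoid, erythroid and megakaryocyte, and fibroblast and epithelial markers had medians of 0.14, 0.09 and 0.04 (adjusted p = 0.0811, 0.169 and 0.173), with FAP at 4.36 ± 0.30 and the platelet glycoprotein gene GP9 at 0.98 ± 0.15 as their 2 members that rose, also adjusted over the list alone.

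**Figure D1:**
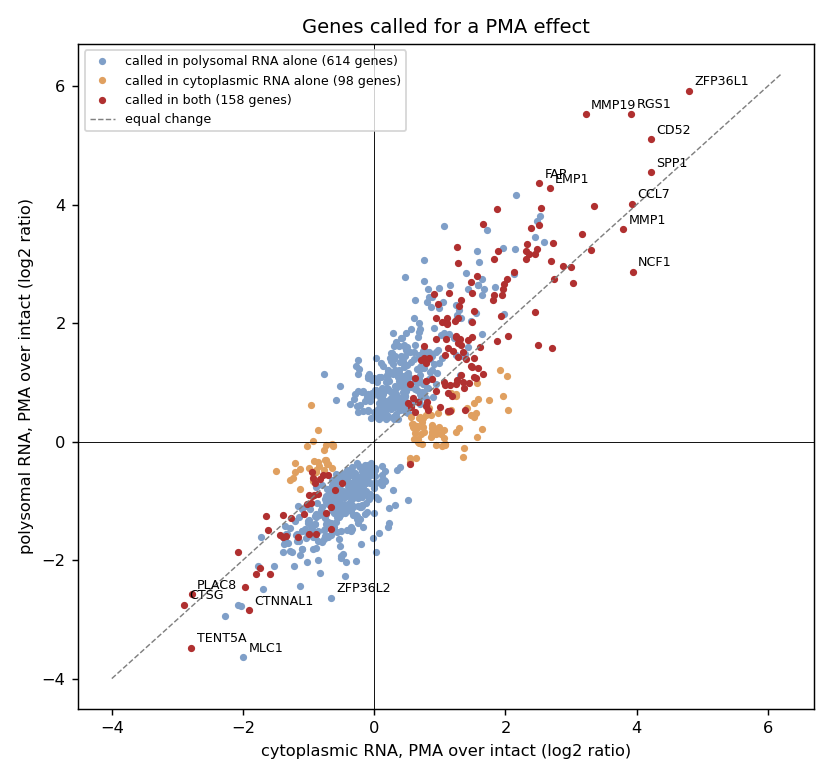
Log2 ratio of PMA-treated over intact cells in cytoplasmic RNA (horizontal axis) against that in polysomal RNA (vertical axis), 1 point per gene called in either, coloured by where it was called. The dashed line marks equal change, and 120 genes were higher and 37 lower in both, with ZFP36L1 at the top right and CTSG among the lowest.

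Over all genes limma called 772 changed by PMA in polysomal RNA, 426 higher and 346 lower, of which 444 changed at least 2-fold. These counts include a dye bias left in replicate 1, whose forward array carried that bias with the opposite sign. With the mean dye bias removed, a step chosen after the data were seen, 504 genes were higher and 220 lower. The 2 replicates correlated at r = 0.520 across genes, against 0.795 to 0.861 in the other comparisons. Both RNA pools shared 120 higher and 37 lower genes, where independent lists would share 5.69 and 1.61. Both calls used the same fitted spread of each gene, so part of that excess was built in. The melanocyte gene LRMDA, named after its values were seen, was higher in cytoplasmic (0.55 ± 0.07) and lower in polysomal RNA (-0.38 ± 0.07). The ratios of the pools correlated at r = 0.732 across genes, which are not independent replicates. Scaling the arrays to one spread gave 641 higher and 845 lower genes, and the arrays of this comparison alone called 0, with 1840 genes at an unadjusted p under 0.05. Without replicate 1 or replicate 2 of this comparison 209 genes (183 higher and 26 lower) and 87 genes (64 and 23) were called. Without either replicate of the cytoplasmic PMA comparison 369 were called.

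Polysomal over cytoplasmic RNA in intact cells asked which messages were held on ribosomes relative to their cytoplasmic amount. In all, 26 of 67 ribosomal protein genes were called lower. RPS2, a protein of the small ribosomal subunit, was lower in polysomal RNA (-3.76 ± 0.35, n = 2, adjusted p = 0.00391), as were FTL (-3.85 ± 0.17, adjusted p = 0.00101), the cytoplasmic actin gene ACTG1 (-3.67 ± 0.23, adjusted p = 0.00158) and LYZ, which encodes lysozyme (-3.58 ± 0.24, adjusted p = 0.00178). The lowest ratio among called genes belonged to RPL7L1 (-4.55 ± 0.33, adjusted p = 0.00211), a relative of a ribosomal protein gene. HNRNPA1L2 and RPL10L, copies of more abundant genes that a probe may also read, stood at -4.28 ± 0.30 and -3.59 ± 0.89. GAA, the lysosomal alpha-glucosidase gene, was 8.56-fold higher in polysomal RNA (3.10 ± 0.43, adjusted p = 0.00920), and DPP8, a dipeptidyl peptidase gene, was 7.05-fold higher (2.82 ± 0.29, adjusted p = 0.00478).

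All 67 measured ribosomal protein genes had mean ratios below 0, with a median of -1.30, which was -2.05 in replicate 1 and -0.56 in replicate 2. Over all genes 26 were called lower, and 50 were adjusted over the list alone (adjusted p = 2.32e-15, but adjusted p = 0.868 with an estimated correlation). RPS28 followed RPS2 at -3.57 ± 0.46. Of 43 translation factors 16 were lower and 1 higher, and 21 lower and 3 higher adjusted over the list alone, with a median of -0.73 (adjusted p = 6.28e-05, but adjusted p = 0.868 with an estimated correlation). Low members were TPT1 at -3.49 ± 0.69, EIF5A at -3.16 ± 0.18 and the poly(A)-binding protein gene PABPC1 at -2.46 ± 0.27, while EIF3B, named after its value was seen, was higher at 0.86 ± 0.15. In the iron and ferritin list 5 of 13 were lower and 1 higher (6 and 1 adjusted over the list alone), with the transferrin receptor gene TFRC at -2.09 ± 0.52 beside FTL. Its median was -0.38 (adjusted p = 0.0363, but adjusted p = 0.868 with an estimated correlation). Cell cycle genes had 17 of 68 lower and none higher (20 and 2 adjusted over the list alone), with the topoisomerase gene TOP2A at -2.67 ± 0.45 and CCNE2, which encodes cyclin E2, at -2.37 ± 0.29. MYC and ribosome biogenesis genes had 5 of 34 lower (9 adjusted over the list alone), with the spermidine synthase gene SRM at -2.05 ± 0.25. The secretory list had 13 of 48 lower and 2 higher (18 and 4 adjusted over the list alone), with the disulfide isomerase gene P4HB at -2.81 ± 0.28. Medians of these 3 lists were -0.28, -0.47 and -0.53 (adjusted p = 0.0363, 0.0355 and 0.0363), and for each the call was lost at adjusted p = 0.868 with an estimated correlation. Replicates 1 and 2 gave -0.26 and -0.21, -0.76 and -0.20, and -0.41 and -0.37 for these 3 lists. They gave -1.16 and -0.41 for translation factors and -0.40 and -0.11 for iron genes.

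Several lists had no shift called by camera, most with members on both sides. Respiratory chain genes had 13 higher and 8 lower of 65 (19 and 12 adjusted over the list alone), proteasome genes 6 and 7 of 31 (7 and 10), lysosome genes 2 and 5 of 40 (5 and 8), interferon genes 2 and 5 of 41 (the same counts adjusted over the list alone) and cholesterol genes 2 and 2 of 20 (3 and 3). Their adjusted p were 0.762, 0.651, 0.700, 0.700 and 0.182. The activator subunit gene PSME2 was higher (1.95 ± 0.15) and the core subunit gene PSMB3 lower (-2.89 ± 0.51). Macrophage markers had 3 higher and 9 lower of 51 (5 and 13 adjusted over the list alone, adjusted p = 0.176), progenitor and granule genes 7 lower of 20 (7 adjusted over the list alone, adjusted p = 0.0538, but lower in fry at adjusted p = 0.0485), cytokines 1 higher and 1 lower of 39 (1 lower adjusted over the list alone, adjusted p = 0.712) and NF-kB genes 1 and 4 of 41 (also adjusted over the list alone, adjusted p = 0.712). The calprotectin gene S100A9 was lower (-2.79 ± 0.48), and LGALS3 was higher (1.63 ± 0.32). Markers of lymphoid, erythroid and megakaryocyte, and fibroblast and epithelial cells had 0 members passing in limma, over all genes or adjusted over the list alone, where 5014 of all genes had an unadjusted p under 0.05 (adjusted p = 0.659, 0.314 and 0.712 for the lists). Median and test differed in sign for the respiratory chain (median -0.29, test up), lymphoid markers (median -0.00441, mean 0.00166, test up) and fibroblast and epithelial markers (median -0.02, mean 0.02, test up), and interferon genes had a median of 0.06 and a mean of -0.05. Only 2 of 8 nuclear-retained RNAs were measured and that list was not tested. Of these long noncoding RNAs TUG1 was lower in polysomal RNA (-1.42 ± 0.18, adjusted p = 0.00713). MALAT1, named after its value was seen, stood at 0.22 ± 0.08 (adjusted p = 0.0999). Adjusted over the list alone 1 was higher and 1 lower.

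Over all genes limma called 2277, 659 higher and 1618 lower in polysomal RNA, and 1020 of them differed at least 2-fold. The balance was 2219 higher and 2773 lower in a closed loop, 2044 and 2779 with a dye coefficient whose sign was turned for 1 array, and 17 and 118 without replicate 1. The arrays of this comparison alone called 0 genes, with 3769 at an unadjusted p under 0.05, and without its replicate 1 or 2 the count was 135 or 1177, and 1334 without either replicate of the cytoplasmic PMA comparison.

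**Figure D2:**
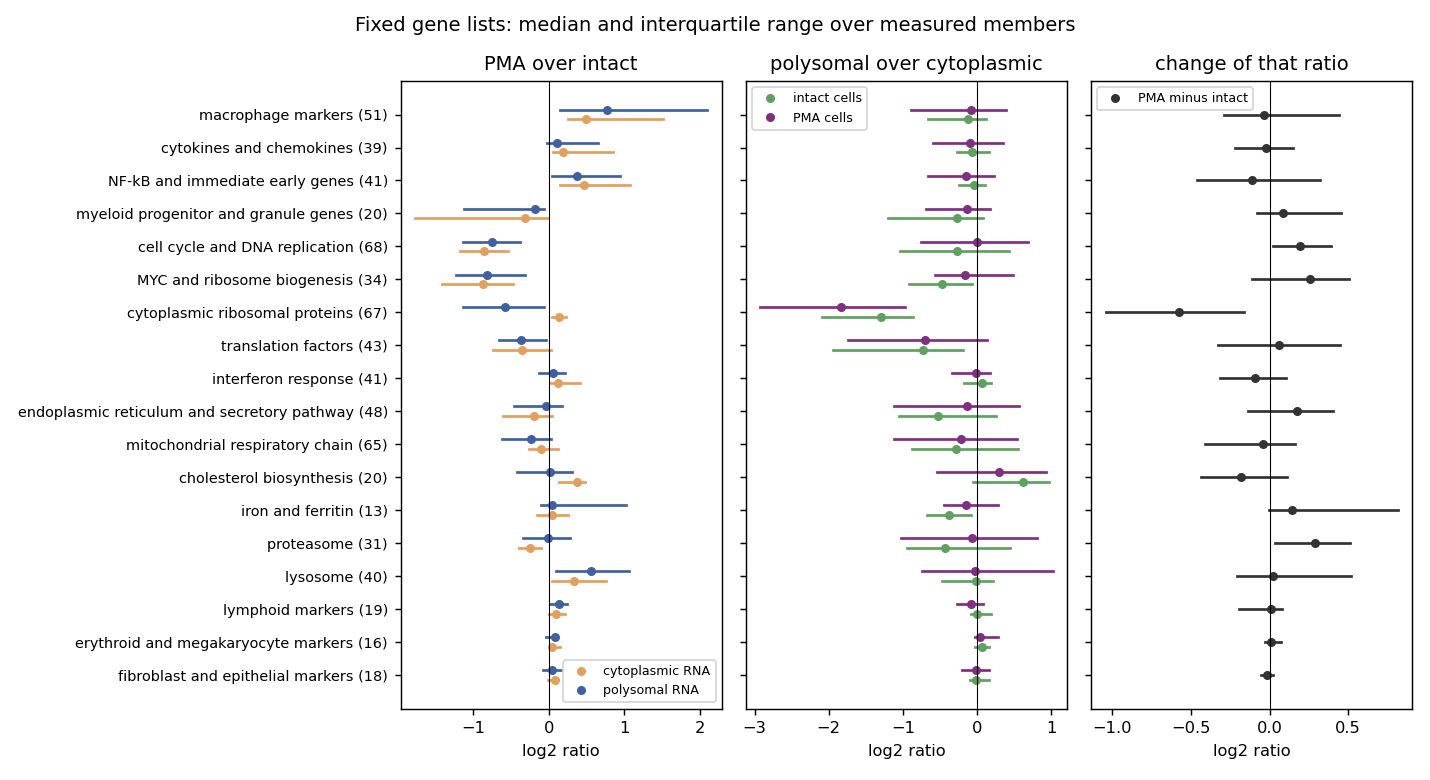
Median (point) and interquartile range (line) of log2 ratios over the measured members of 18 gene lists, with member numbers in brackets, for PMA over intact cells (left), polysomal over cytoplasmic RNA (middle) and the change of that ratio with PMA (right). Ribosomal protein genes lie lowest in the middle panel, at -1.30 in intact and -1.84 in PMA-treated cells, and macrophage markers lie at 0.50 and 0.78 in the left panel.

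In PMA-treated cells 54 of 67 ribosomal protein genes were called lower in polysomal RNA, and translation factors were called both ways. RPS19, RPS28 and RPS2 were at -4.64 ± 0.97, -4.51 ± 0.46 and -4.37 ± 0.35 (n = 2, adjusted p = 0.0163, 0.00221 and 0.00117), and TMSB10, an actin-binding peptide gene, was at -4.32 ± 0.43 (adjusted p = 0.00210). LYZ was at -3.94 ± 0.24 (adjusted p = 7.36e-04) and LIMS1, an adaptor of integrin signalling, at -4.13 ± 0.16 (adjusted p = 4.90e-04). DPP8 was 11.6-fold higher in polysomal RNA (3.54 ± 0.29, adjusted p = 0.00126), MMP19 was also higher (3.33 ± 0.22, adjusted p = 8.44e-04) and RANBP2, a nuclear pore protein gene, 8.23-fold higher (3.04 ± 0.33, adjusted p = 0.00256).

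Ribosomal protein genes had a median of -1.84, with 54 of 67 lower over all genes, 65 adjusted over the list alone and none above 0 (adjusted p = 4.67e-15, but adjusted p = 0.966 with an estimated correlation). Translation factors had 22 of 43 lower and 6 higher, 23 and 7 adjusted over the list alone, with EIF3F at -3.42 ± 0.38 and the elongation factor gene EEF1G at -2.91 ± 0.35. Their median was -0.70 (adjusted p = 0.0305, but adjusted p = 0.966 with an estimated correlation). Camera called no other list, although many held called members on both sides. Fry called macrophage markers, cytokines and chemokines, NF-kB genes, and iron and ferritin genes lower, each at adjusted p = 0.0324. Macrophage markers had 6 higher and 15 lower of 51 (6 and 17 adjusted over the list alone), with NCF1 at -3.18 ± 0.36 and CTSZ at -2.14 ± 0.28. Cytokines and chemokines had 7 higher and 9 lower of 39 (9 and 9), with CCL5 at -2.69 ± 0.28, CXCL8 at -1.63 ± 0.15 and IL1B at 1.14 ± 0.33. NF-kB genes had 7 higher and 14 lower of 41 (the same counts adjusted over the list alone), with ATF3 at 2.30 ± 0.26 and JUN, an early response transcription factor gene, at -1.82 ± 0.25. Their adjusted p were 0.708, 0.833 and 0.596.

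Proteasome genes had 12 higher and 8 lower of 31 (13 and 8 adjusted over the list alone), lysosome genes 11 and 11 of 40 (12 and 14), respiratory chain genes 17 and 15 of 65 (19 and 19), secretory genes 12 and 14 of 48 (13 and 17), cell cycle genes 8 and 14 of 68 (8 and 14) and interferon genes 5 and 8 of 41 (5 and 8). Their adjusted p were 0.732, 0.931, 0.892, 0.833, 0.833 and 0.833. The mitotic kinetochore gene NDC80 was higher (2.82 ± 0.62) and TOP2A lower (-2.46 ± 0.45), and PSME2 was higher (2.09 ± 0.15) and PSMB3 lower (-3.44 ± 0.51). Progenitor and granule genes had 1 higher and 4 lower of 20, MYC and ribosome biogenesis genes 1 and 5 of 34, iron genes 1 and 5 of 13 and cholesterol genes 4 and 5 of 20 (adjusted p = 0.804, 0.833, 0.804 and 0.833), and adjusted over the list alone these became 1 and 4, 0 and 2, 2 and 5, and 5 and 5. FTL was at -2.85 ± 0.17, and SQLE, which encodes squalene epoxidase, was higher (2.42 ± 0.74, adjusted p = 0.0479). Lymphoid, erythroid and megakaryocyte, and fibroblast and epithelial markers had 2, 3 and 3 members higher and none lower (1, 0 and 2 adjusted over the list alone, adjusted p = 0.833, 0.708 and 0.892 for the lists), with FAP at 2.54 ± 0.30. Median and test differed in sign for the proteasome (median -0.07, test up), the respiratory chain (median -0.22, test up) and fibroblast and epithelial markers (median -0.02, mean 0.10, test up), and lysosome genes had a median of -0.03 and a mean of 0.02. Of the nuclear-retained RNAs TUG1 was lower (-1.25 ± 0.18, adjusted p = 0.00519). MALAT1, named after its value was seen, stood at 0.24 ± 0.08 (adjusted p = 0.0570), and 1 was higher and 1 lower adjusted over the list alone.

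Over all genes limma called 5028, 2344 higher and 2684 lower, and 1888 of them differed at least 2-fold. Intact and PMA-treated cells shared 541 higher and 1351 lower genes, against 109 and 305 for independent lists, and 14 genes were called in opposite directions (r = 0.860 across genes). Here too the shared fitted spread of each gene built in part of the excess. Scaling the arrays to one spread lowered the count to 2805, and without replicate 1 or 2 of this comparison it was 1287 (530 higher and 757 lower) or 1134 (342 and 792).

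The change of the polysomal over cytoplasmic ratio with PMA was measured as the mean of its estimates from the PMA comparisons and from the fraction comparisons. Across genes these 2 estimates correlated at r = 0.772 in replicate number 1 and 0.928 in number 2, against -0.02 and 0.161 across numbers. The model took them as independent, so the SE and adjusted p of this change are likely too small. Among called genes MMP19 gained most in polysomal RNA relative to cytoplasmic RNA (2.77 ± 0.22, n = 2, adjusted p = 0.0160), followed by the myeloid lectin gene CLEC5A (2.35 ± 0.27, adjusted p = 0.0284). The DNA glycosylase gene TDG gained 2.01 ± 0.17 (adjusted p = 0.0197) and CD53, a leukocyte tetraspanin gene, 1.97 ± 0.13 (adjusted p = 0.0150). EVA1B was the lowest called gene at -2.09 ± 0.33 (adjusted p = 0.0479), and CISH, an inhibitor of cytokine receptor signalling, was at -1.46 ± 0.15 (adjusted p = 0.0225). BEX1 and BEX2, close relatives whose probes may read each other, stood at -1.69 ± 0.23 and -1.59 ± 0.24.

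Macrophage markers had 4 members with a raised ratio, among them ANXA1 (1.44 ± 0.20) and the receptor gene CSF1R (1.05 ± 0.13), and CD68 had a lowered ratio (-0.72 ± 0.11), with 6 raised and 5 lowered of 51 adjusted over the list alone. That list had a median of -0.03, a mean of 0.07 and a test that pointed up (adjusted p = 0.845). Of the NF-kB genes ATF3 gained (1.88 ± 0.26) and IER3 and MAFF lost (-0.82 ± 0.10 and -0.62 ± 0.09), 5 and 11 of 41 adjusted over the list alone (adjusted p = 0.210). CXCL8 was the 1 cytokine called over all genes (-1.18 ± 0.15, adjusted p = 0.0333), with 1 higher and 2 lower of 39 adjusted over the list alone (adjusted p = 0.821). In the lysosome list CTSA and LAMP1 gained (1.12 ± 0.17 and 1.04 ± 0.16) and PSAP lost (-0.82 ± 0.11), 7 and 3 of 40 adjusted over the list alone (adjusted p = 0.222). The proteasome list shifted upward (median 0.29, adjusted p = 2.25e-04, but adjusted p = 0.939 with an estimated correlation), with PSMC1 and PSMD2 called at 0.97 ± 0.11 and 0.64 ± 0.08 and 8 of 31 higher adjusted over the list alone. Cell cycle genes and secretory genes also shifted upward, with medians of 0.20 and 0.17 (adjusted p = 0.0198 and 0.0495), both lost at adjusted p = 0.939 with an estimated correlation. Cell cycle genes had 0 of 68 called by limma either way, while 2256 of all genes had an unadjusted p under 0.05, and CALR was the 1 secretory gene called (1.06 ± 0.10), also adjusted over the list alone. Ribosomal protein genes shifted downward with 0 of 67 called either way (median -0.57, adjusted p = 8.63e-05, but adjusted p = 0.939 with an estimated correlation). Each of these 4 shifts lay in 1 replicate number. In numbers 1 and 2 the medians were 0.02 and -1.22 for ribosomal proteins, 0.53 and 5.23e-04 for the proteasome, -0.36 and 0.73 for the cell cycle and -0.00975 and 0.37 for secretory genes.

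The 10 other tested lists were not called as a whole by camera or fry. COX6C was the 1 of 65 respiratory chain genes called, over all genes and adjusted over the list alone (-0.94 ± 0.10). Adjusted over the list alone 4 of 13 iron genes gained, 4 of 43 translation factors gained and 1 lost, and 1 interferon gene and 1 fibroblast and epithelial gene gained. Progenitor and granule, MYC and ribosome biogenesis, cholesterol, lymphoid, and erythroid and megakaryocyte genes had 0 called either way. Medians were -0.04 for the respiratory chain, 0.14 for iron, 0.06 for translation factors, -0.09 for interferon genes, 0.09 for progenitor and granule genes, 0.25 for MYC and ribosome biogenesis and -0.18 for cholesterol genes. Their adjusted p ran from 0.0611 for iron genes to 0.845 for the respiratory chain. Lymphoid markers had a median of 0.01, a mean of -0.06 and a test that pointed down, and fibroblast and epithelial markers a median of -0.02, a mean of 0.09 and a test that pointed up (adjusted p = 0.797 and 0.845).

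**Figure D3:**
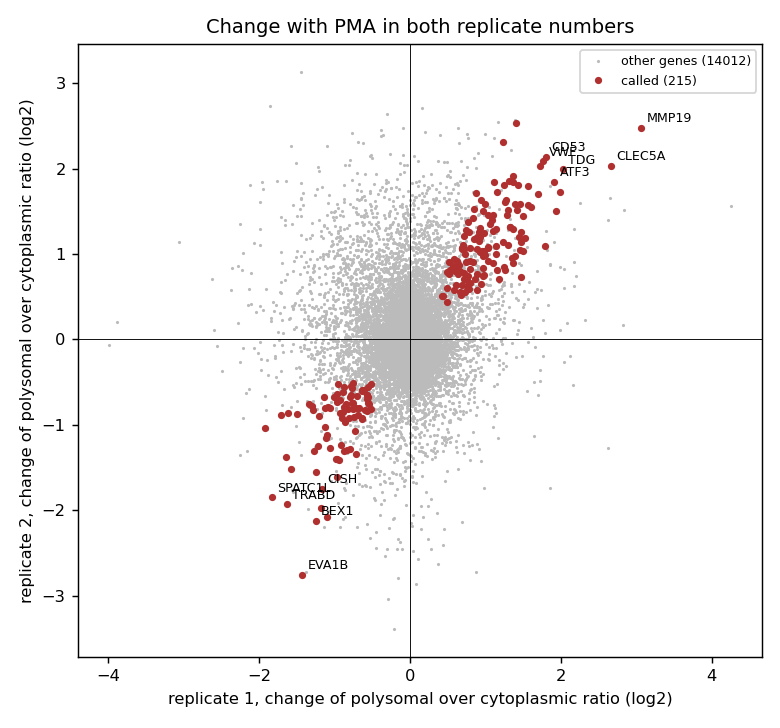
Change with PMA of the polysomal over cytoplasmic log2 ratio in replicate number 1 (horizontal axis) and replicate number 2 (vertical axis), 1 point per gene, with the 215 called genes in red and the others in grey. The called genes lie on the same side of 0 in both numbers. The test itself fixes this, since its spread holds the difference of the numbers, so it is no sign of replication. Over all genes the numbers correlate at r = 0.0912.

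Over all genes limma called 215, 133 with a raised and 82 with a lowered ratio, of which 109 changed at least 2-fold. The call count depended on how the 4 comparisons were combined: with the loop of each replicate number taken as 1 value limma called 0 genes (1048 at an unadjusted p under 0.05), the replicate number as a block left 28, and the PMA comparisons or the fraction comparisons alone called 0 (884 and 1271 at an unadjusted p under 0.05). Without replicate 1 of the polysomal PMA comparison 76 genes were called, and 0 without any 1 of the other 7 replicates, with 1491 to 2357 genes at an unadjusted p under 0.05.

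**Figure D4:**
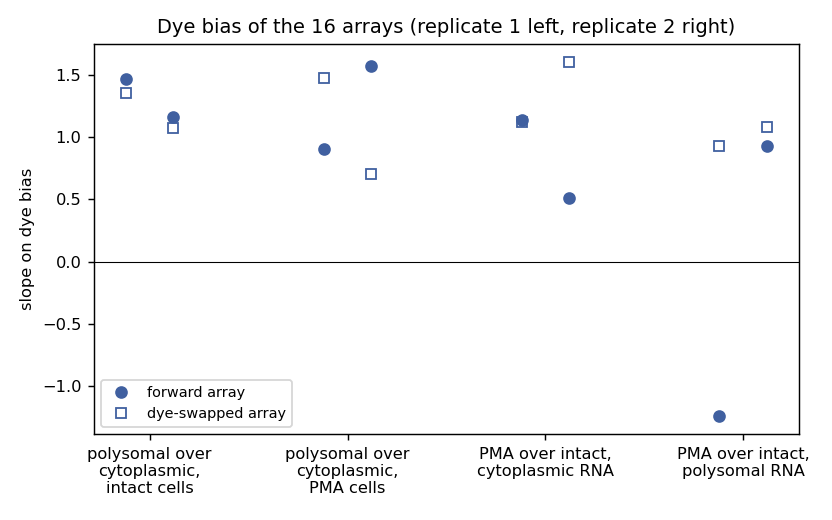
Slope of each array's deposited log ratios on the probe-wise dye bias of the arrays (vertical axis, no unit), by comparison (horizontal axis), with filled circles for forward and open squares for dye-swapped arrays. The forward array of replicate 1 in polysomal RNA, PMA over intact cells, lies at -1.24, and the 15 others lie between 0.515 and 1.61.

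The deposited values of that forward array, used in the polysomal PMA comparison and in the change of ratio, carried the dye bias with the opposite sign. Its swapped partner had a slope of 0.925, so the bias did not cancel in their mean and stayed in the main fit. Without the forward array limma called 677 genes in polysomal RNA, 396 higher and 281 lower, and 199 for the change of ratio. That setting kept only the swapped partner in that replicate, so the partner's own dye bias was not averaged out. Removing the mean dye bias from that replicate gave 724 genes in polysomal RNA, 504 higher and 220 lower. Only 611 of the 772 genes called by the main fit were among them. For the change of ratio the removal gave 408 genes, with 204 of the 215 genes among them.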

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

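The tests of explanations in this part, the removal of the dye bias and the fit with 1 value per replicate number were chosen after the result was seen, while the change of ratio, the gene lists and the estimated correlation were planned.

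The forward array of replicate 1 in polysomal RNA, PMA over intact cells, stood apart from the other 3 arrays of its comparison in the slope of its values on the dye bias (-1.24), in its number of exact zeros (0) and in its median (0.0133). Over named probes alone the slope was -1.08. A near-absence of exact zeros was not particular to it, as the forward array of replicate 1 in cytoplasmic RNA, PMA over intact cells, had 1. Of 16 such checks of array measures 3 passed Dixon's 95% critical value for 4 samples, all on this array, where chance passes about 1 in 20 groups. An array hybridised in the swapped orientation and inverted afterwards could give this. The slope of -1.24, outside the 0.515 to 1.61 of the 15 other arrays, is what flagged the array and is no separate test. The array's PMA effect kept its sign, with a correlation with replicate 2 of r = 0.445 across probes, as such an inversion would leave it. An exact copy of its swapped partner is argued against by a standard deviation of 0.0902 for the sum of the 2 arrays. A rescan of the partner's slide stays open. It would put the standard deviation of the sum below that of any other 2 arrays, and 0.0902 was 0.855 times their lowest (0.105). The array's correlation with the partner (r = -0.904) lay outside that of the 7 other pairs (-0.685 to -0.112) and also goes with a rescan. A dye bias carried alike by both arrays could give both values too, so they cannot decide. No biological explanation was tested.

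CCL3 was the 1 of 80 named genes past the same value, with 6.38 on the forward array of replicate 2 in polysomal RNA, PMA over intact cells, above its other 3 arrays.

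The change of the polysomal over cytoplasmic ratio between PMA-treated and intact cells was itself a tested difference, and limma called 215 genes for it. Arrays of the same replicate number may share RNA extracts, since loops of the same number summed to 0.243 times the variance of the 14 loops that mixed numbers (0.102 and 0.0423 against a mean of 0.296). This went mainly with PMA cytoplasmic and intact polysomal RNA and was not shown for all 4 sources. The 2 mixed loops that kept those numbers together had variances of 0.0698 and 0.157, the first of them below that of replicate 1. The lowest of the other mixed loops, at 0.123, lay below the second of them, so the loops were not cleanly parted. Shared extracts may have added to the count. Simulated errors shared in all 4 sources gave a median of 21.5 calls and at most 51. Those errors were drawn separately for each gene, while related genes varied together in the data (estimated correlation 0.877 for ribosomal proteins). The simulation therefore cannot say whether shared extracts could give 215. Dye bias left in replicate 1 of polysomal RNA is argued against as the whole cause, because 94.9% of the genes stayed called once it was removed. A change of ribosome loading shared by both replicate numbers stays open, as the numbers correlated at only r = 0.0912 across genes, and at 0.176 with the dye bias removed. With 1 value per number limma called 0 genes (1048 at an unadjusted p under 0.05).

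The genes with the largest raised ratios were MMP19 at 2.77, CLEC5A at 2.35, TDG at 2.01, CD53 at 1.97, CD164 at 1.97 and VWF at 1.92. They were followed by ATF3 at 1.88, ARNT2 at 1.88, HNRNPK at 1.86 and GLCE at 1.77. Those with the largest lowered ratios were EVA1B at -2.09, SPATC1L at -1.84, TRABD at -1.78, BEX1 at -1.69 and BEX2 at -1.59. ENC1 at -1.57, RILPL2 at -1.55, CITED4 at -1.51, PURB at -1.48 and CISH at -1.46 came next. Gene lists with a called shift of the ratio were cell cycle and DNA replication (0.20), ribosomal proteins (-0.57), the endoplasmic reticulum and secretory pathway (0.17) and the proteasome (0.29), each lost with an estimated correlation. None was shared by both replicate numbers, whose medians were -0.36 and 0.73, 0.02 and -1.22, -0.00975 and 0.37, and 0.53 and 5.23e-04 in the same order.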

How the results depend on the processing

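The settings that removed a dye bias or turned the dye sign, read values in base 2, crossed replicate numbers, took 1 value per replicate number, left out the array with the reversed dye bias or included unnamed probes were chosen after the data were seen; the others were planned. Counts are given for PMA in cytoplasmic and polysomal RNA, the fractions in intact and PMA-treated cells, and the change of ratio. Main counts were 256, 772, 2277, 5028 and 215. A 2-fold minimum gave 155, 444, 1020, 1888 and 109, and in base 2 it gave 8, 27, 15, 34 and 0. All 16 arrays with a dye coefficient gave 1289, 1734, 4119 and 932 (all but PMA-treated fractions), and 1641, 1696, 4823 and 1359 with the dye sign turned for 1 array. A closed loop gave 1436, 1604, 4992 and 542 for the same. Scaling to one spread gave 1057, 1486 and 2805 for PMA in both pools and for PMA-treated fractions. Forward arrays alone gave 436 for polysomal RNA and 13 for the change of ratio, and swapped arrays alone 2683, 1689 and 3551 for the first 3. A comparison's own arrays gave 1379 for cytoplasmic RNA and 0 for polysomal RNA and intact fractions (1840 and 3769 at an unadjusted p under 0.05, lowest adjusted p 0.0761 and 0.119). The PMA or the fraction comparisons alone gave 0 for the change of ratio (884 and 1271), as did 1 value per replicate number (1048, and 1255 with the dye bias removed). Removing the dye bias gave 408.

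Leaving out each replicate gave 0 to 197, 87 to 544, 135 to 2584, 1134 to 5465 and 0 to 76 genes, where a lone replicate was assumed to vary like the others. With the replicate number as a replicate block the counts were 254, 674, 2260, 4903 and 28, and no other count moved over 1.5 times. Deviations of the numbers correlated at -0.782 and -0.804 between comparisons that share PMA cytoplasmic or intact polysomal RNA with opposite sign, as shared extracts would give, and at -0.15 to 0.269 between the others, so the numbers were not shown to pair all 4 RNA sources. Crossed numbers gave 254, 765, 2219, 4991 and 187 calls.

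Of 33 list calls 3 held with an estimated correlation, and fry called 18, of which 12 were shared. Ribosomal proteins and the respiratory chain turned from lower in polysomal RNA with PMA to 0.0573 and 0.0605 without replicate 2, against -1.28 and -0.60 without replicate 1. Over 353 named-gene results, 7105 of 8655 alternative values kept direction and side of the threshold, 1375 fell short of it, 160 newly passed it and 15 turned sign, all uncalled. MALAT1 turned in polysomal RNA with PMA to 0.00489 (dye sign turned), 0.00462 (dye bias removed) and a range of -0.12 to 0.0226 without a replicate, in cytoplasmic RNA to -0.00714 (swapped arrays) and in the change of ratio to 0.0142 (fraction comparisons). MYC turned in the change of ratio to 0.0933 (swapped arrays) and 0.0612 (fraction comparisons), with a range of -1.06 to 0.68 without a replicate, and in PMA-treated fractions ranged from -2.28 to 1.21. TUG1 in polysomal RNA with PMA ranged from -0.43 to 0.0411. On forward arrays CD14 stood at -0.0384 in intact fractions, and HBA2 and RPLP1 at -0.12 and -0.37 with PMA in cytoplasmic RNA. The cause was not tested, except that a 2-fold minimum and base 2 lower counts by construction. Keeping genes with missing values was not run, as no value was missing, and without intensities the limit set by signal over background is unknown.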

Other observations

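In this part the test of ribosomal protein messages against abundant transcripts was chosen after the result was seen, and those against dye bias and short span were set before.

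Outside the groups, other cytoplasmic messages changed by PMA were those of CD52, a small leukocyte surface glycoprotein, at 4.22 ± 0.33 (n = 2, adjusted p = 0.00791) and RGS1 at 3.91 ± 0.28 (adjusted p = 0.00622), while TENT5A, a poly(A) polymerase gene, fell by 2.79 ± 0.26 (adjusted p = 0.0124). In polysomal RNA the membrane protein gene EMP1 rose (4.28 ± 0.16, adjusted p = 3.18e-04), as did NCR1, a receptor gene of natural killer cells (4.16 ± 0.36, adjusted p = 0.00424). CXCL8 rose in cytoplasmic RNA with PMA (1.53 ± 0.15, adjusted p = 0.0136) and was lower in polysomal than in cytoplasmic RNA of PMA-treated cells (-1.63 ± 0.15, adjusted p = 0.00159). Both ratios hold cytoplasmic RNA of PMA-treated cells, with opposite sign. Deviations of these comparisons correlated at -0.782 across genes, so an error in that source could move both values of CXCL8.

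Ribosomal protein messages stood low in polysomal RNA, with medians of -1.30 in intact and -1.84 in PMA-treated cells and 0 of 67 members above 0 in the mean. The size differed between replicates in intact cells (-2.05 and -0.56) and hardly in PMA-treated cells (-1.85 and -1.83). Dye bias is argued against, since the list median lay below 0 on 8 of 8 arrays of both dye orientations, at most -0.25, although 1 array missed the bound of -0.5 set beforehand. Short gene span, the length on the genome with introns, is argued against too, as removal of the span trend left -1.27 and -1.77. Span tracked the ratios only weakly (rank correlations of 0.119 and 0.153), and the length of the message itself was not tested. The list's call itself was lost with an estimated correlation (adjusted p = 0.868 and 0.966). A bias of the normalization against abundant messages could not be told apart without intensities. Respiratory chain genes stood at -0.22 or lower in median but both ways among members. In intact cells their median turned sign, at -0.58 in replicate 1 and 0.29 in replicate 2, while ribosomal proteins stayed below 0 in both. A lower ribosome load of ribosomal protein messages was not tested and stays open beside that bias.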
